A study of Mus musculus with 6 samples.

How the data were processed

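Total RNA from flash-frozen colon tumour tissue of C57BL/6 mice was sequenced in 6 libraries, per the labels' protocols. Groups were taken from the sample titles, 3 Ilf3-WT and 3 Ilf3-KO libraries. The count column of the sample titled replicate 4 of the knockout carries the number 2 in its header, and the title was used. The authors deposited 1 file per library with raw counts per gene, whole numbers that were not normalized. HISAT2 and the mouse genome build mm10 are named in the submitters' processing notes, without a version of the aligner. The counting program, its annotation release, its strand setting and its treatment of reads that match several places are not given in the sources used here. Genes with near-identical copies, pseudogenes, overlapping genes and antisense partners are therefore uncertain, since their reads could have been split or shared.

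Each file held 55166 rows, of which 54446 named a gene. The 720 rows without a gene name took 0.461% to 0.629% of counts and stayed out of library sizes and tests. Gene identifiers were matched to GENCODE release M21 on GRCm38, the assembly also called mm10, and 54409 were found there. Coordinates are 1-based. Depth ranged from 16282641 to 19467024 counts per library, and the 10 genes with the most counts took 4.74% to 5.86% of them. Counts come from reads without molecular identifiers, so counting error is a lower limit on the error of a value.

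From the deposited counts, edgeR 4.0.16 in R 4.3.3 was used with TMM normalization and filterByExpr (a minimum count of 10 and a minimum total of 15), which kept 17680 genes. The main test was the quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest) of genotype, two-sided, without covariates, over all 6 libraries, with Benjamini-Hochberg adjusted p under 0.05. SEs of log2 fold changes come from the same fit. Log2 CPM for tests of single values used a prior count of 2. Medians of B cell and MHC class II genes in the tests of explanations used log2 of mean CPM plus 0.1, so they differ slightly from the medians of edgeR fold changes given elsewhere, and CPM plus 0.5 or 1 was tried after seeing the data. Gene lists, 45 in all, covered pathways tied to Ilf3, double-stranded RNA, metabolism and immunity, markers of cell types a colon tumour piece could hold, and signs of RNA quality. They were tested with camera (preset correlation 0.01 and, beside it, an estimated correlation) and fry from limma 3.58.1, with a minimum of 5 tested members and adjustment over the lists. Fry called 13 lists as moving on balance in a single direction and 42 as changing in either direction. Neither fry test compares a list with other genes.

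Named genes followed a rule. Ilf3 and Ilf2 were always named. So were the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap and whose mean was at least 1 CPM, leaving out identifiers without a gene symbol and immunoglobulin or T cell receptor variable segments. In each list, up to 4 members with the smallest p-values could be named, members past the threshold first. Samples, lists, designs, named gene rule and most alternatives were fixed before the data were examined.

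Libraries were compared in pairs by the variance of their counts beyond Poisson error, over genes with at least 20 summed counts. Ilf3-WT replicates 1 and 2 differed by more than counting noise (median chi-square per gene 0.731, where counting alone gives 0.455), as did Ilf3-KO replicates 1 and 3 (0.747), which repeat libraries of the same RNA can show as well. All 6 were kept as samples because the titles number them as replicates, and the sums of close pairs were set beside them. Alternatives were DESeq2 1.42.0 size factors and its Wald test, library size scaling, limma-voom, no filter and a filter at 5 CPM, each library left out, the replicate number as a block, and removal of mitochondrial, immunoglobulin and haemoglobin genes. A log2 fold change of at least 1, an adjusted p under 0.1 and an estimated correlation were tried as well. Alternatives added after seeing the data were the sums of close pairs, Ilf3-KO replicate 4 alone against wild type, removal of Y-linked genes and Xist, and inclusion of rows without a gene name.

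The scripts were tested on simulated data over 17680 genes, drawn from the means, library sizes and gene dispersions of the fit to all 6 libraries. Simulated libraries were independent and held no close pairs. The shares and false calls below therefore do not describe data with close pairs. With 3 against 3 libraries, 35.8% of genes changed 1.5-fold, 71.6% of genes changed 2-fold and 87.9% of genes changed 4-fold were recovered, with 15 false calls. With 2 against 2 the shares were 11.9%, 53.7% and 75.8%. A simulation without any difference gave 3 calls. A simulated list of 20 members was recovered, with 0 other lists called. Genes were drawn independently, whereas the estimated correlation in the real lists reached 0.891 (type I interferon-stimulated genes). The simulation therefore does not show how the preset correlation performs on correlated genes.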

Results

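RNA was measured in 6 colon tumour samples from C57BL/6 mice treated with azoxymethane (AOM), a carcinogen, and with dextran sulfate sodium (DSS), which injures the colon lining and causes colitis. Per the labels, AOM was given at 10 mg/kg and DSS in 3 rounds. The samples formed 2 genotype groups of 3 libraries each, wild type (Ilf3-WT replicates 1, 2 and 3) and knockout (Ilf3-KO replicates 1, 3 and 4). The question posed by the series was how loss of Ilf3, which encodes a double-stranded RNA binding protein, changes gene expression in these tumours. Total counts per library were 16282641, 17004146 and 18097085 for Ilf3-WT replicates 1, 2 and 3. They were 19452331, 19288727 and 19467024 for Ilf3-KO replicates 1, 3 and 4. After a filter on low counts, 17680 genes were tested. Levels are TMM-normalised CPM, given as mean ± SD over the 3 libraries of a group, and fold changes are knockout over wild type with the SE on the log2 scale.

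The targeted gene was examined first. Ilf3 (ENSMUSG00000032178, chromosome 9, 21367871 to 21405361 in GRCm38) had 1553, 1552 and 1606 counts in Ilf3-WT replicates 1, 2 and 3 and 890, 843 and 813 counts in Ilf3-KO replicates 1, 3 and 4. Its level was 91.1 ± 2.96 CPM in wild type and 44.7 ± 1.46 CPM in knockout tumours, 49.1% of wild type (log2 fold change -1.03 ± 0.063, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.78e-04). An exact two-sided permutation test of the log2 values gave p = 0.1, the smallest p that 3 against 3 libraries allow. Counts per gene do not show which exons the remaining reads covered, or whether every allele and every cell had lost the gene. Ilf2 (chromosome 3, 90476126 to 90488379), whose product pairs with the Ilf3 protein, had 135 ± 3.43 CPM in wild type and 139 ± 14.8 CPM in knockout libraries (log2 fold change 0.05 ± 0.081, edgeR adjusted p = 0.754).

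As lists, MHC class II and goblet cell genes rose in the knockout tumours, and macrophage, neutrophil and type I interferon-stimulated genes fell, the last with 9 of 29 members past the test. The calls of goblet cells (adjusted p = 0.142 with an estimated correlation), macrophages (adjusted p = 0.0658 with an estimated correlation) and interferon-stimulated genes (adjusted p = 0.438 with an estimated correlation) were lost in the camera setting that estimates the correlation between genes. Cd74 (chromosome 18, 60803848 to 60812652), the MHC class II invariant chain, rose from 426 ± 9.95 to 875 ± 18.6 CPM, and Ciita (chromosome 16, 10480059 to 10528418), the master transactivator of MHC class II genes, rose 3.75-fold. Retnlb (chromosome 16, 48816856 to 48818892), a goblet cell product, had the largest rise among the named genes, from 3.27 ± 1.85 to 160.0 ± 62.0 CPM (log2 fold change 5.60 ± 0.50). The Retnlb call was lost with close pairs summed (edgeR adjusted p = 0.0690). Lcn2 (chromosome 2, 32384633 to 32388252), an iron-sequestering antimicrobial protein, fell 4.59-fold, and Csf1r (chromosome 18, 61100598 to 61132149), the macrophage colony-stimulating factor receptor, fell from 56.8 ± 5.37 to 27.3 ± 0.986 CPM.

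Across the 17680 genes, 2220 passed an edgeR adjusted p of 0.05, of which 937 were higher and 1283 lower in the knockout. In each of these 2220 genes the 3 knockout libraries lay beyond the 3 wild-type libraries, as did 35.6% of all tested genes. Scaling by library size alone called 716 higher and 1513 lower, so that 32.1% of calls were higher against 42.2% here. A change of at least 1 on the log2 scale was reached by 617 genes, 181 higher and 436 lower.

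The libraries of a group were not evenly spaced. Ilf3-WT replicates 1 and 2 differed by a coefficient of variation of 3.16% beyond counting error, and Ilf3-KO replicates 1 and 3 by 3.84%. The remaining library of each group lay at 9.94% to 10.2% (Ilf3-WT replicate 3) and 20.8% to 21.2% (Ilf3-KO replicate 4) from the others. Ilf3-KO replicates 1 and 3 also held Y-linked reads (Ddx3y 1888 and 1825 counts, Xist 1264 and 1135 counts), whereas the other 4 libraries had 0 to 2 Ddx3y counts and 17471 to 19311 Xist counts. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be partly technical. With the counts of each close pair summed, giving 2 samples per group, 63 genes passed (20 higher, 43 lower), all within the 2220. Ilf3-KO replicate 4 was also set alone against the 3 wild-type libraries. It took part in the main calls and lay beyond the wild-type libraries in all 2220 genes, so values from it alone are not independent support. Leaving out single libraries gave 588 genes without Ilf3-WT replicate 1, 590 without Ilf3-WT replicate 2, 1303 without Ilf3-KO replicate 1, 1243 without Ilf3-KO replicate 3 and 4516 without Ilf3-KO replicate 4.

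**Figure D1:**
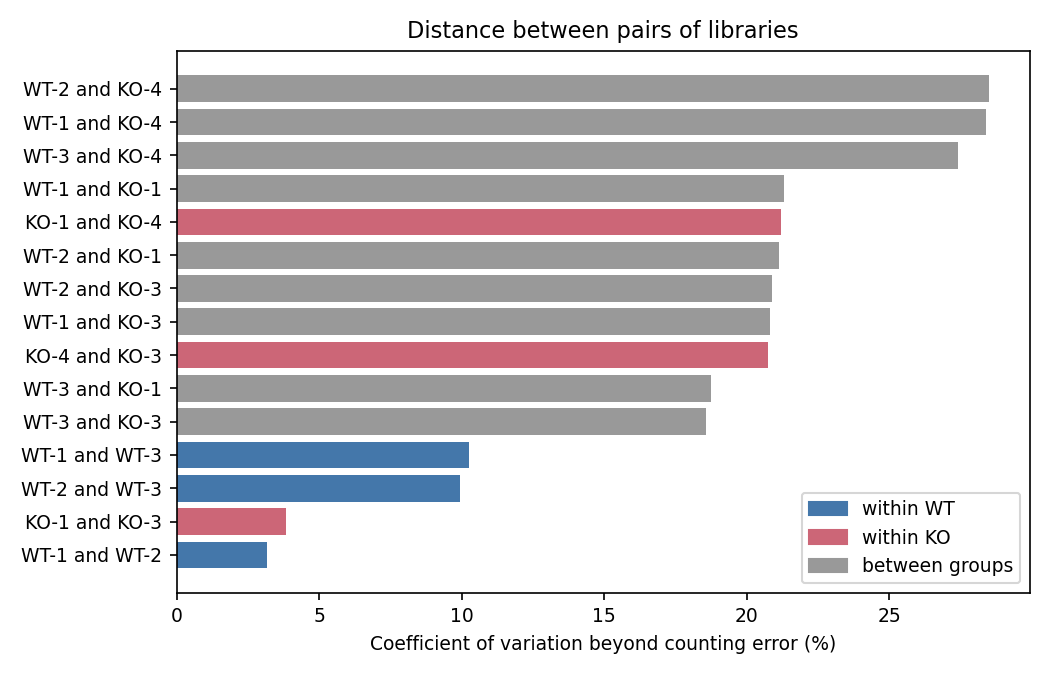
Horizontal bars show, for each of the 15 pairs of libraries, the coefficient of variation beyond counting error in percent, coloured by pairs within wild type, within knockout or between groups. Ilf3-WT 1 and 2 (3.16%) and Ilf3-KO 1 and 3 (3.84%) lie closest, and pairs between groups span 18.6% to 28.5%.

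The genes with the largest rises that passed the test, after Retnlb, included B3gnt6 (log2 fold change 3.27 ± 0.37), an enzyme that builds mucin O-glycans, Igf2bp1 (2.86 ± 0.33), an oncofetal RNA-binding protein, Gpc3 (2.58 ± 0.23), a glypican, and Cdx2 (2.42 ± 0.36), the intestinal homeobox transcription factor. Tagln3 (3.81), Ctrb1 (3.62), Gldn (3.35), Scgb2b10 (2.82, annotated as a pseudogene), Pcolce2 (2.74), Greb1 (2.47) and Foxd2 (2.43) completed the 12. The largest falls were those of Trpv5 (-3.79 ± 0.47), an epithelial calcium channel, Atp1a2 (-3.25 ± 0.30), a sodium-potassium ATPase subunit, Tspan32 (-3.16 ± 0.16), a tetraspanin, Pcna-ps2 (-3.14), a pseudogene whose reads can be shared with Pcna, and H19 (-2.99 ± 0.41), an imprinted non-coding RNA. Wdr72 (-2.83), Ggt1 (-2.73), Pkd2l1 (-2.71), Gkn3 (-2.65), Tgm4 (-2.64), the pseudogene Zfp783 (-2.64) and Ighg1 (-2.60) followed. The edgeR adjusted p for these 24 genes ranged from 8.82e-05 (Tspan32) to 0.0161 (Foxd2). Calls were lost without Ilf3-WT replicate 1 or 2 for Cdx2 (highest adjusted p 0.0553), Scgb2b10 (0.0846), Pcolce2 (0.0833) and Foxd2 (0.0816, also without Ilf3-WT replicate 3), without Ilf3-WT replicate 2 for Ctrb1 (0.0762) and without Ilf3-WT replicate 1 for Gldn (0.0562). Calls went without Ilf3-KO replicate 4 for H19 (0.0755) and Tgm4 (0.05004), and without each of the knockout libraries in turn for Ighg1 (up to 0.0635). Without Ilf3-WT replicate 3 the log2 fold change was 6.18 for Retnlb, 5.46 for Ctrb1, 3.95 for Scgb2b10, 3.68 for Pcolce2 and -1.93 for Ighg1, and without Ilf3-KO replicate 4 that of Foxd2 was 1.83. With close pairs summed, B3gnt6, Gpc3, Tspan32, Pcna-ps2, Wdr72, Ggt1 and Zfp783 kept an adjusted p under 0.05. Retnlb (0.0690) and Cdx2 (0.107) were among those that did not.

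**Figure D2:**
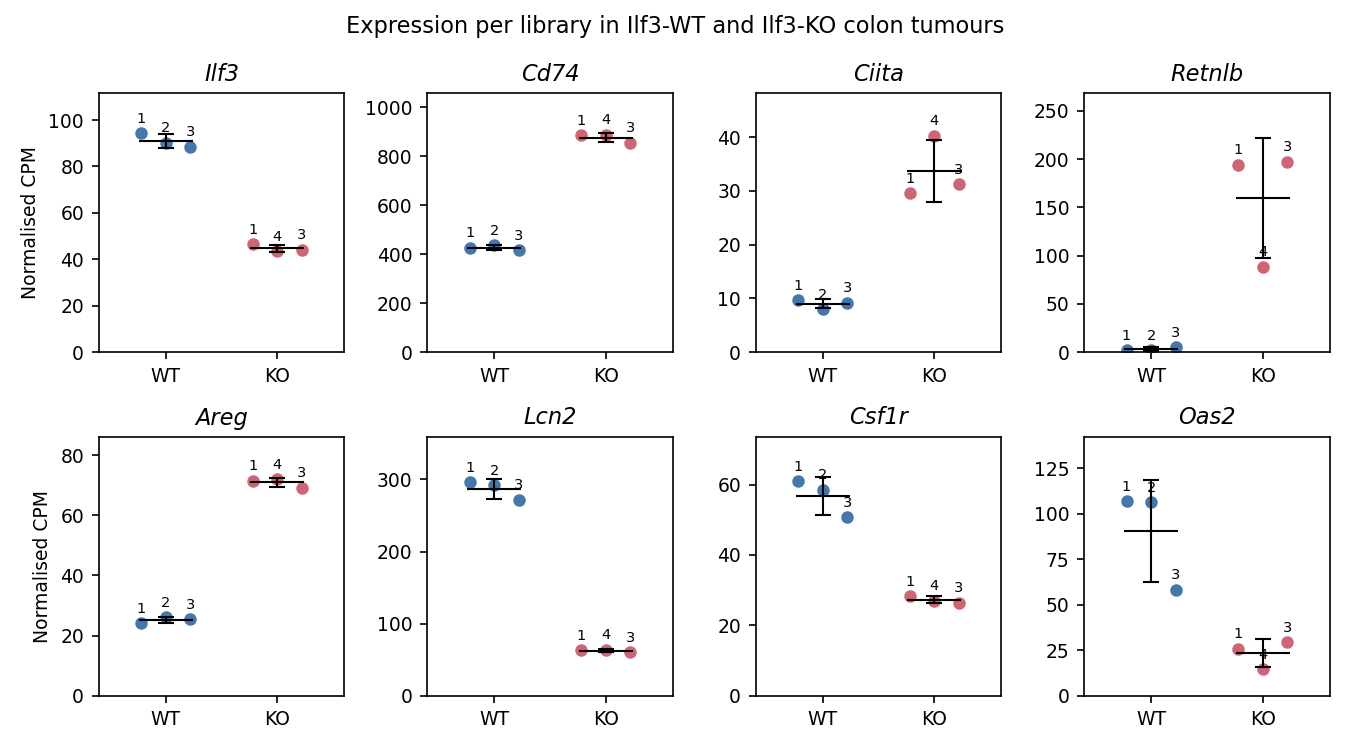
Points show normalised CPM of 8 genes in each library, numbered by replicate, with the mean (long bar) and SD (error bars) of the 3 libraries per genotype. Cd74, Ciita, Retnlb and Areg lie higher and Ilf3, Lcn2, Csf1r and Oas2 lower in all 3 knockout libraries, with Cd74 at 426 ± 9.95 CPM in wild type and 875 ± 18.6 CPM in knockout.

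Gene lists fixed before the data were examined were then compared, and the genes named from them kept their call with each library left out in turn unless stated. With close pairs summed, 125 of the 148 named genes past the threshold, other than Ilf3, lost their call. The camera test with a preset inter-gene correlation of 0.01 called 26 of 45 lists, 14 upward and 12 downward. With an estimated correlation 2 lists were called, MHC class II antigen presentation and neutrophils. With close pairs summed, an alternative with 27 calls at the preset value, the smallest adjusted p was 0.265 with an estimated correlation. That setting raised p-values also where the estimate was not above the preset or lay near it. For acinar pancreas and small intestine the estimate was 0.0106, and the camera adjusted p went from 4.39e-07 to 0.0658. For dendritic cells it was -0.036, and the camera adjusted p went from 0.00296 to 0.142. Correlation between members therefore does not account for the calls lost in these lists. Among MHC class II genes, 7 of 10 tested members rose and none fell, with 7 called when adjusted over the list alone (median log2 fold change 0.99, camera adjusted p = 2.51e-20, adjusted p = 0.0173 with an estimated correlation). Besides Cd74 and Ciita, the class II beta chains H2-Ab1 (122 ± 3.38 to 235 ± 20.98 CPM) and H2-Eb1 (123 ± 2.92 to 217 ± 6.53 CPM) rose, and these 4 genes also passed with close pairs summed (adjusted p 0.0306 to 0.0455). In Ilf3-KO replicate 4 alone the list median was 0.97. Markers of B cells, which also express these genes, summed to 88.7 CPM in Ilf3-KO replicate 4, to 34.8 and 37.3 CPM in Ilf3-KO replicates 1 and 3, and to 46.0 to 51.6 CPM in wild type.

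Genes of the interferon-gamma response, which can induce Ciita, were mixed. Of 23 members 5 rose and 1 fell, with 9, 7 higher and 2 lower, called when adjusted over the list alone (median 0.13, camera adjusted p = 0.0163, adjusted p = 0.615 with an estimated correlation). Ciita is shared with the MHC class II list, and Nos2, the inducible nitric oxide synthase, was the member that fell (-0.78 ± 0.094). The list call was lost without Ilf3-KO replicate 1 (adjusted p = 0.129) and without Ilf3-KO replicate 3 (0.0838), and the median, 0.228 and 0.222 without Ilf3-WT replicates 1 and 2, was -0.0161 and 0.0372 in those leave-outs. The call was also lost with limma-voom (adjusted p = 0.0714), with a filter at 5 CPM (0.0672) and with close pairs summed (0.0653). Without Ilf3-KO replicate 4 the median was 0.402, and in Ilf3-KO replicate 4 alone it was -0.45. In MHC class I antigen presentation 4 of 20 members rose (5 adjusted over the list alone), among them the immunoproteasome subunit Psmb10 (0.60 ± 0.088), with a camera adjusted p of 0.0130 and an adjusted p of 0.537 with an estimated correlation. That call was lost without Ilf3-WT replicate 3 (adjusted p = 0.0602), Ilf3-KO replicate 1 (0.0594) or Ilf3-KO replicate 3 (0.0566).

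Macrophage and monocyte markers fell in 18 of 21 cases and rose in none, with 19 called when adjusted over the list alone (median -0.94, camera adjusted p = 1.07e-23, adjusted p = 0.0658 with an estimated correlation). Cd14, a lipopolysaccharide co-receptor, went from 115 ± 4.32 to 65.3 ± 2.08 CPM, and the complement gene C1qa from 74.9 ± 5.14 to 38.9 ± 3.25 CPM. Cd14, Csf1r and C1qa passed also with close pairs summed (adjusted p 0.0439 to 0.0487). Neutrophil markers fell in 8 of 18 cases and rose in none, with 9 called when adjusted over the list alone (median -0.46, camera adjusted p = 6.65e-18, adjusted p = 0.0173 with an estimated correlation). Besides Lcn2, which intestinal epithelium also makes, the iron-binding protein Ltf fell 4.93-fold, Retnlg 3.74-fold and the calprotectin subunit S100a8 1.98-fold, and all 4 passed with close pairs summed. In Ilf3-KO replicate 4 alone the medians were -1.06 for macrophages and -0.68 for neutrophils. These falls stood beside a rise of epithelial markers (median 0.24, adjusted p = 0.296 with an estimated correlation).

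T cell markers fell in 5 of 20 cases (6 adjusted over the list alone; median -0.48, camera adjusted p = 9.42e-04, adjusted p = 0.257 with an estimated correlation). The T cell receptor kinase Lck was at 11.1 ± 1.05 CPM in wild type and 5.93 ± 0.400 CPM in knockout. Regulatory T cell and checkpoint genes fell in 3 of 13 cases (10 adjusted over the list alone; camera adjusted p = 5.37e-04, adjusted p = 0.290 with an estimated correlation). Entpd1, an ectonucleotidase (-0.50, highest adjusted p 0.0938), and Il2ra, the interleukin receptor chain CD25 (-1.03, 0.0888), lost their calls without Ilf3-WT replicate 1, Ilf3-WT replicate 2 or Ilf3-KO replicate 3, and Entpd1 also without Ilf3-KO replicate 1. Inflammatory cytokine and chemokine genes fell in 7 of 26 cases and rose in none (14, 1 higher and 13 lower, adjusted over the list alone; median -0.77, camera adjusted p = 2.10e-06, adjusted p = 0.438 with an estimated correlation). The neutrophil chemoattractant Cxcl3 fell from 17.9 ± 1.11 to 7.16 ± 1.52 CPM, and the related Cxcl5 from 400.2 ± 11.2 to 163 ± 49.1 CPM. The Cxcl5 call was lost without Ilf3-WT replicate 1 or 2 (highest adjusted p 0.0566). Without Ilf3-KO replicate 4 the list median was -0.501. Dendritic cell markers fell in 4 of 14 cases and rose in 1 (camera adjusted p = 0.00296, adjusted p = 0.142 with an estimated correlation; 6, 1 higher and 5 lower, called when adjusted over the list alone), and the chemokine Ccl22 fell 2.96-fold. In Ilf3-KO replicate 4 alone the medians were -0.51 for T cells, -0.87 for regulatory and checkpoint genes, -1.62 for cytokines and -0.72 for dendritic cells.

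Type I interferon-stimulated genes fell in 9 of 29 cases and rose in none, and 24 were called when adjusted over the list alone. The median log2 fold change was -0.9975 (camera adjusted p = 1.54e-12, adjusted p = 0.438 with an estimated correlation). Ddx58, which encodes the RNA sensor RIG-I, fell from 87.2 ± 13.8 to 51.5 ± 1.73 CPM. Oas2, an oligoadenylate synthetase, had the lower level in the knockout (90.5 ± 27.9 to 23.2 ± 7.67 CPM, adjusted p = 0.0168). Its call was lost without Ilf3-WT replicate 1, Ilf3-WT replicate 2, Ilf3-KO replicate 1 or Ilf3-KO replicate 4 (highest adjusted p 0.0654). Ilf3-WT replicates 1 and 2 lay above replicate 3 for Oas2, at 107 and 106 against 58.2 CPM. With close pairs summed the adjusted p was 0.104 for Ddx58 and 0.156 for Oas2, and in Ilf3-KO replicate 4 alone the median was -1.52. Partners of the Ilf3 product and other double-stranded RNA binding proteins had 0 of 16 members called, also when adjusted over the list alone (median -0.06, camera adjusted p = 0.477), with the RNA editing enzyme Adar at -0.33 ± 0.092 and adjusted p = 0.0516. In the same list the RNA-activated kinase Eif2ak2 had -0.34 ± 0.12 and adjusted p = 0.110.

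Goblet cell genes rose in 9 of 16 cases and fell in none (10 adjusted over the list alone; median 0.75, camera adjusted p = 2.19e-10, adjusted p = 0.142 with an estimated correlation). Besides Retnlb, Spink4 rose from 129 ± 24.6 to 243 ± 9.40 CPM and Atoh1, the transcription factor that directs the secretory lineage, from 6.99 ± 2.34 to 19.7 ± 2.28 CPM. General epithelial genes rose in 8 of 17 cases (9 adjusted over the list alone; median 0.24, camera adjusted p = 6.74e-05, adjusted p = 0.296 with an estimated correlation). Krt8 rose (log2 fold change 0.45 ± 0.074), a call lost without Ilf3-WT replicate 1 or 2 (highest adjusted p 0.0630). Colonocyte genes went both ways, with 5 of 18 higher and 2 lower (11, 9 higher and 2 lower, adjusted over the list alone; camera adjusted p = 0.00738, adjusted p = 0.438 with an estimated correlation). The carbonic anhydrase Car2 rose from 202 ± 6.27 to 397 ± 20.1 CPM, and the sodium-proton exchanger Slc9a3 fell from 436 ± 74.3 to 147 ± 34.5 CPM. In Ilf3-KO replicate 4 alone the medians were 0.61 for goblet cells, 0.30 for epithelium and 0.40 for colonocytes.

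Paneth cell and secretory niche genes rose in 3 of 12 cases (6, 5 higher and 1 lower, adjusted over the list alone; camera adjusted p = 0.0110, adjusted p = 0.438 with an estimated correlation). The Paneth list call was lost without Ilf3-KO replicate 4 (adjusted p = 0.0609). Lyz1, which encodes lysozyme, went from 552 ± 66.8 to 931 ± 77.8 CPM, although reads of Lyz1 can be shared with its close paralog Lyz2. Genes of acinar pancreas and small intestine rose in 6 of 10 cases (6 adjusted over the list alone; median 2.41, camera adjusted p = 4.39e-07, adjusted p = 0.0658 with an estimated correlation). Their levels were low, with the enterocyte lipid carrier Fabp2 at 1.78 ± 0.396 CPM in wild type and 8.78 ± 3.36 CPM in knockout and the chymotrypsinogen gene Ctrb1 at 0.223 ± 0.291 and 2.91 ± 0.977 CPM. Squamous epithelium genes fell in 4 of 9 cases (4 adjusted over the list alone; camera adjusted p = 0.0184, adjusted p = 0.537 with an estimated correlation). The desmosomal cadherin Dsg3 was at -1.38 ± 0.15. That list call was lost without Ilf3-KO replicate 4 (adjusted p = 0.236), without Ilf3-WT replicate 3 (0.0701) and with limma-voom (0.0641). Its median, -0.32 over all libraries, was 0.0733 without Ilf3-KO replicate 4, -0.514 without Ilf3-KO replicate 1 and -0.617 without Ilf3-KO replicate 3.

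**Figure D3:**
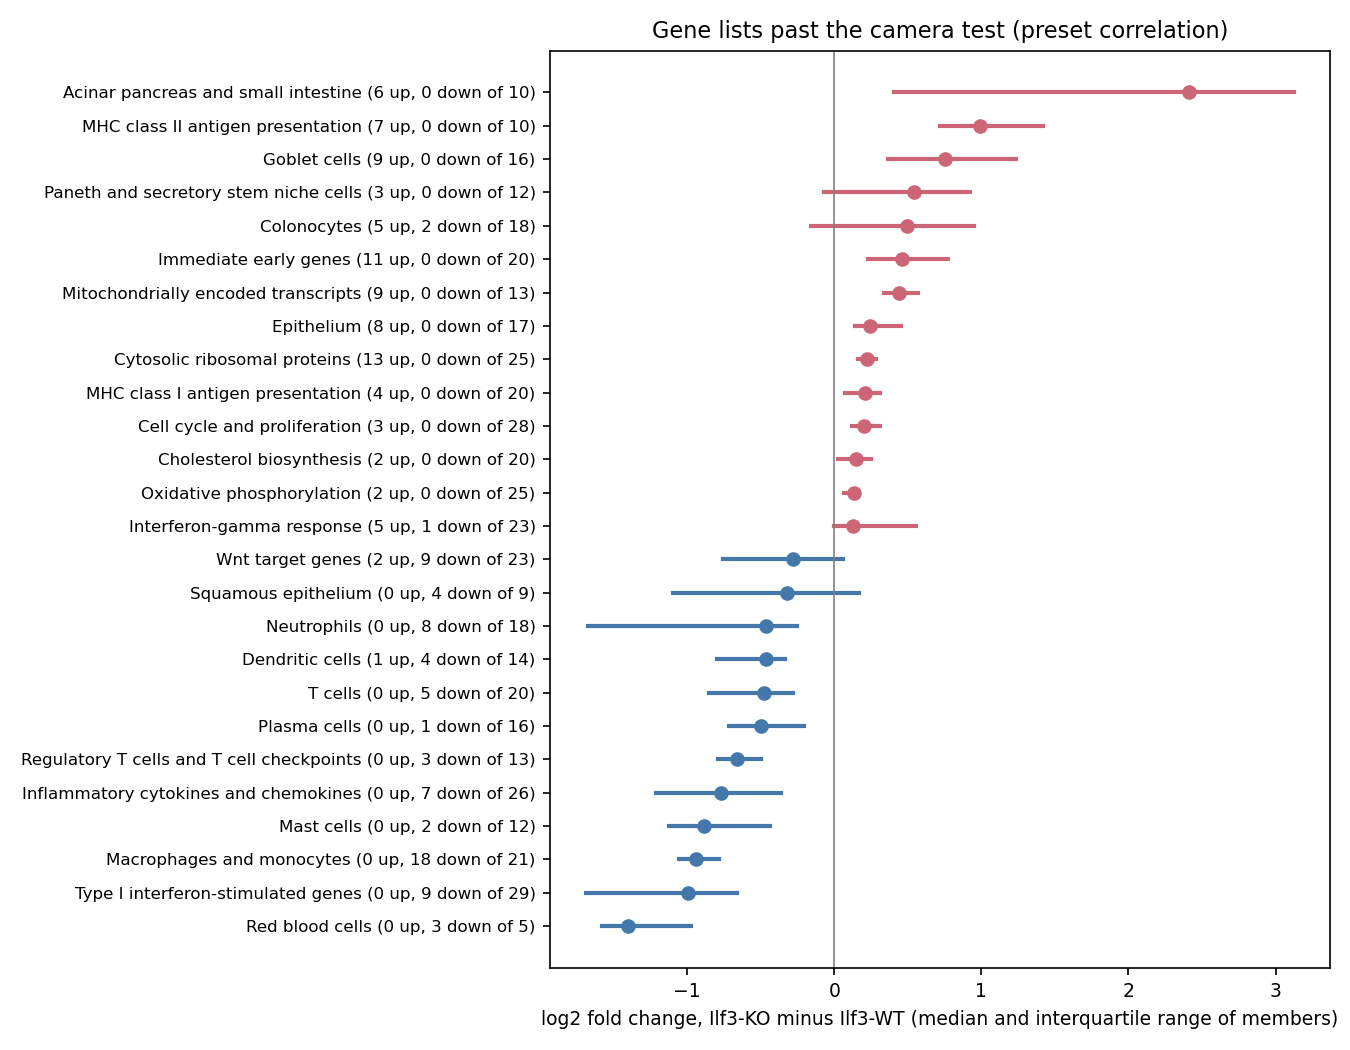
Points show the median and lines the interquartile range of log2 fold changes, knockout minus wild type, over the tested members of the 26 lists called by camera with the preset correlation, with the numbers of members called in each direction. Medians run from -1.40 (red blood cells) to 2.41 (acinar pancreas and small intestine), and only MHC class II and neutrophils were also called with an estimated correlation.

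Wnt target genes fell in 9 of 23 cases and rose in 2 (18, 6 higher and 12 lower, adjusted over the list alone; median -0.28, camera adjusted p = 9.42e-04, adjusted p = 0.438 with an estimated correlation). Members that fell included Wif1 (721 ± 64.5 to 299 ± 52.1 CPM) and Dkk3 (123 ± 1.11 to 57.0 ± 13.1 CPM), of which Wif1 encodes a secreted Wnt inhibitor, and the transcription factor Lef1 (-0.63 ± 0.10). The list median was -0.552 without Ilf3-KO replicate 1 and -0.446 without Ilf3-KO replicate 3. Intestinal stem cell genes went both ways, with 2 of 17 higher and 4 lower (8, 4 higher and 4 lower, adjusted over the list alone), and the list was not called (camera adjusted p = 0.885, with a positive median of 0.04 and a test direction downward). Lgr5, the crypt base stem cell receptor, fell from 122 ± 18.6 to 78.4 ± 1.84 CPM and Smoc2 from 204 ± 6.51 to 128 ± 2.44 CPM. Among EGFR ligands and MAPK feedback genes, 4 of 18 rose and 2 fell (10, 5 higher and 5 lower, adjusted over the list alone; camera adjusted p = 0.422). Areg (chromosome 5, 91139599 to 91148432), the EGFR ligand amphiregulin, rose 2.81-fold from 25.2 ± 0.966 to 70.9 ± 1.497 CPM, and the ERK-responsive transcription factor Etv5 fell 2.89-fold, both also with close pairs summed (adjusted p 0.0164 and 0.0265). Regenerative and fetal-like epithelial genes rose in 2 of 18 cases and fell in 3 (7, 4 higher and 3 lower, adjusted over the list alone; camera adjusted p = 0.922, median 0.01, mean -0.15, test direction upward). The secreted phosphoprotein Spp1 was at -1.67 ± 0.26.

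Of the metabolic lists, serine, glycine and one-carbon metabolism had 3 of 25 members lower and none higher (4, 1 higher and 3 lower, called when adjusted over the list alone; camera adjusted p = 0.961, median 0.02, mean -0.01, test direction upward). The folate enzyme Aldh1l1 fell from 267 ± 4.91 to 154 ± 20.3 CPM. ATF4 and amino acid stress targets had 1 of 22 higher and 2 lower (4, 2 higher and 2 lower, adjusted over the list alone; camera adjusted p = 0.991, with a positive median, a mean of -0.06 and a test direction upward), and the cystine transporter Slc7a11 was at -1.11 ± 0.21. The latter call was lost without Ilf3-WT replicate 1 or 2 (highest adjusted p 0.0736). In glycolysis and hypoxia 1 of 21 rose and 4 fell (9, 5 higher and 4 lower, adjusted over the list alone; camera adjusted p = 0.991), with Pfkfb3, an activator of glycolysis, at -0.77 ± 0.092. Oxidative phosphorylation genes rose in 2 of 25 cases (camera adjusted p = 0.0118, adjusted p = 0.537 with an estimated correlation; 1 adjusted over the list alone), and cholesterol biosynthesis genes in 2 of 20 (camera adjusted p = 0.0215, adjusted p = 0.438 with an estimated correlation; 3 adjusted over the list alone). The cholesterol list lost its call with close pairs summed (adjusted p = 0.0695) and with a filter at 5 CPM (0.0509). Cell cycle genes rose in 3 of 28 cases (3 adjusted over the list alone; camera adjusted p = 0.00337, adjusted p = 0.686 with an estimated correlation). That list call was lost without Ilf3-KO replicate 4, where the median went from 0.20 to 0.04 (adjusted p = 0.316).

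Transcripts that track sample handling and RNA composition differed between the groups too. Mitochondrially encoded transcripts took 3.15% to 3.45% of counts in wild-type and 3.84% to 4.45% in knockout libraries, and 9 of 13 rose (11 adjusted over the list alone; median 0.44, camera adjusted p = 1.05e-07, adjusted p = 0.112 with an estimated correlation). Cytosolic ribosomal protein genes rose in 13 of 25 cases (16 adjusted over the list alone; median 0.22, camera adjusted p = 5.33e-07, adjusted p = 0.142 with an estimated correlation), although many have processed pseudogenes that can share their reads. Immediate early and heat shock genes, which respond within minutes to tissue handling, rose in 11 of 20 cases (12 adjusted over the list alone; median 0.46, camera adjusted p = 3.26e-09, adjusted p = 0.325 with an estimated correlation). Their median was 0.692 without Ilf3-KO replicate 4. Fos rose from 166 ± 4.26 to 338 ± 40.1 CPM and the heat shock gene Hspa1a from 8.24 ± 1.03 to 22.99 ± 1.81 CPM, the latter nearly identical in sequence to Hspa1b. Replication-dependent histone genes, a sign of RNA without poly(A) tails, had 0 of 10 members called, also when adjusted over the list alone (camera adjusted p = 0.983, median -0.01, test direction upward).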

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

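Among the tests of explanations below, those on B cells, with their pseudocounts, and on macrophages or dendritic cells were chosen after the rise of MHC class II genes was seen, and the others were set beforehand.

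Rows without a gene name, which the comparison left out, also differed between the genotypes. Of 450 such rows with enough counts to test, 81 passed the edgeR threshold, 37 higher and 44 lower in the knockout. Their sequences and coordinates were not used here.

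Ilf3-WT replicates 1 and 2 resembled each other far more than replicate 3, and Ilf3-KO replicates 1 and 3 far more than replicate 4. Immunoglobulin variable segments, whose usage depends in part on an animal's own B cell clones, correlated across 126 segments with a Spearman rho of 0.879 in the wild-type pair and 0.858 in the knockout pair. The highest rho of any other pair was 0.702, between Ilf3-KO replicates 1 and 4, and segments are not independent replicates. These 2 libraries differed in Y-linked reads, so part of the usage can be shared between animals. The close pairs thus lay above every other pair, as a shared animal or RNA sample would give. The lower value, 0.858, stayed below the level set beforehand for that explanation. Segments with as few as 20 counts summed over the 6 libraries took part, and counting noise can lower rho there. Missing that level is therefore not evidence against a shared animal or sample. Whether the pairs are tumours of the same animal, repeat libraries or similar animals cannot be told apart from counts.

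The 2220 genes that differed by genotype could reflect the lower Ilf3 level, 49.1% of wild type, or differences between single tumours or animals, including sex, and of 6830 genes called between the close pairs, 71.6% had the same sign in Ilf3-KO replicate 4 minus Ilf3-WT replicate 3, libraries that shared no reads with the pairs and both had few Y-linked reads. That share lay above the range set for differences without a genotype effect and below the bound set for excluding them, so these cannot be told apart from a genotype effect with so few independent samples. The share was 60.9% over all tested genes and 78.3% among the 1049 of these genes with a log2 change of at least 1, and the differences between genotypes correlated across all tested genes at 0.404 and 0.445, where those within genotypes correlated at -0.0472. A difference shared by all libraries of a group, such as tissue handling, would repeat in both comparisons as well. The share and the correlations cannot separate it from genotype, and immediate early genes were higher in the knockout in 11 of 20 cases. DNA of another strain around the targeted locus is argued against only as a source of many calls near Ilf3. Within 20 Mb of Ilf3 22 of 209 tested genes were called, 0.837 times the share elsewhere (Fisher's exact test, two-sided, p = 0.461). A few genes changed by such DNA would not show in this share, and it does not bear on calls elsewhere. The real grouping called 2220 genes and the other 9 splits of the 6 libraries at most 0 by edgeR (108 to 1467 genes at an unadjusted p under 0.05, where 884 were expected), so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Each of the other 9 splits mixed the genotypes, which widens the spread within its groups. Few calls were likely there in advance, so the 0 does not measure false calls.

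MHC class II genes rose in all 3 knockout libraries, with sums of 1908, 1867 and 1777 CPM in Ilf3-KO replicates 1, 3 and 4 and 1019 to 1066 CPM in wild type. More macrophages or dendritic cells are argued against, since the median log2 fold change of their 35 markers was -0.83. For the dendritic cell list by itself it was -0.46, with 4 of 14 members lower and 1 higher. These markers bear on the number of cells and not on the amount of MHC class II RNA per cell. More B cells are argued against in Ilf3-KO replicates 1 and 3, where the median of 12 B cell markers, from log2 of CPM plus 0.1, was -0.28 and that of the MHC class II list 0.91 (-0.21 and 0.91 with CPM plus 1). In Ilf3-KO replicate 4 the B cell median was 2.09, above the MHC class II median of 0.96 (1.54 and 0.93 with CPM plus 1), so a contribution of B cells may hold there, although all their markers together summed to 88.7 CPM. MHC class II expression by tumour epithelium in the knockout stays open as a hypothesis, as does more of it per immune cell. Both are untested in bulk tissue, and staining or sorted cells would decide.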

How the results depend on the processing

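The results from summed close pairs, from Ilf3-KO replicate 4 alone, without Y-linked genes and Xist, and with rows without a gene name were chosen after seeing the data. Ilf3 was lower and past the threshold under all 18 other settings in which it was tested, between -1.05 and -0.998 when single libraries were left out and with an adjusted p of 0.0359 when close pairs were summed. The count of 2220 genes became 63 with close pairs summed, 4544 with only Ilf3-KO replicate 4 against wild type, where that lone library is assumed to vary like the wild-type ones, 617 when a log2 fold change of at least 1 was also required and 3479 at an adjusted p under 0.1. It ranged from 588 (without Ilf3-WT replicate 1) to 4516 (without Ilf3-KO replicate 4) when single libraries were left out. Under the other settings it lay between 2033 and 2877, with 2235 for DESeq2 size factors and 2636 for the DESeq2 Wald test, where 5 adjusted p-values were not available. The number of lists called, 26, became 2 with an estimated inter-gene correlation and ranged from 24 to 27 when single libraries were left out. The fall to 2 does not measure correlation alone, since the acinar list, with an estimate of 0.0106 near the preset 0.01, lost its call too. The number of lists called was 29 without a filter on low counts and 19 with a filter at 5 CPM, where 22 of the 26 could still be tested. Without mitochondrial, immunoglobulin and haemoglobin genes it was 23, with 24 of the 26 tested.

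Some lists changed direction. Smooth muscle genes, not called over all libraries, had medians from -0.278 to 0.382 when single libraries were left out. The lowest was that without Ilf3-KO replicate 4 (camera adjusted p = 0.0276). With the replicate block the median was -0.304 (camera adjusted p = 0.00785). Neither fit draws its genotype effect from Ilf3-KO replicate 4. With only Ilf3-KO replicate 4 against wild type the medians were -0.447 for the interferon-gamma response, 0.372 for intestinal stem cells and -0.312 for regenerative epithelium. The cause of these shifts was not tested.

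Of 148 named genes past the threshold, other than Ilf3, 65 kept the call in each of the 6 leave-outs and 83 lost it in at least 1. With close pairs summed 23 kept the call and 125 lost it, and without a filter on low counts 16 lost it. The replicate block gave 2877 genes, 1876 of them among the 2220. It cost 2 of the 26 called lists and 7 of the 148 named genes their calls. Numbers 2 and 4 each occur in 1 group only, so the genotype effect in that fit rests on numbers 1 and 3. For the replicate numbers shared by the groups, deviations from the group means correlated at -0.0494 for number 1 and 0.0266 for number 3. These deviations mostly follow the distance of each close pair from the remaining library of its group. They therefore cannot show whether shared numbers pair the libraries. The change of pseudocount planned for deposited normalized values was not run, as the deposited values are counts. Of simulated 1.5-fold changes, 35.8% were recovered with 3 against 3 libraries and 11.9% with 2 against 2, in simulations without close pairs.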

Other observations

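Haemoglobin and other red blood cell genes fell in 3 of 5 cases (3 adjusted over the list alone; median -1.40, camera adjusted p = 5.10e-04, adjusted p = 0.438 with an estimated correlation). Hba-a1 was at 12.9 ± 0.650 CPM in wild type and 4.89 ± 1.68 CPM in knockout, a call lost without Ilf3-WT replicate 1 (edgeR adjusted p = 0.0511). Mast cell genes fell in 2 of 12 cases (2 adjusted over the list alone; camera adjusted p = 0.00507, adjusted p = 0.438 with an estimated correlation). The mast cell call was lost with a filter at 5 CPM (adjusted p = 0.208). Plasma cell genes fell in 1 of 16 cases (4, 1 higher and 3 lower, called when adjusted over the list alone; camera adjusted p = 0.0200, adjusted p = 0.537 with an estimated correlation). The plasma cell call was lost without Ilf3-KO replicate 1 (adjusted p = 0.0957) or 3 (0.0665), with a filter at 5 CPM (0.0564) and without mitochondrial, immunoglobulin and haemoglobin genes (0.321). Of 78 immunoglobulin variable segments tested, 19 passed, 17 lower and 2 higher in the knockout. Fibroblast and matrix genes fell in 2 of 22 cases (2 adjusted over the list alone; camera adjusted p = 0.0944). These were the metalloproteinase inhibitor Timp1 (18.0 ± 1.28 to 7.95 ± 1.17 CPM) and the metalloproteinase Mmp10 (224 ± 3.54 to 136 ± 21.5 CPM). In the endothelium list 1 of 15 members fell (1 adjusted over the list alone; camera adjusted p = 0.0677), Prox1 (574 ± 21.5 to 321 ± 64.3 CPM), which intestinal tumour epithelium also expresses. Enteric neuron and glia genes had 1 of 8 lower (2 adjusted over the list alone; camera adjusted p = 0.788, with a positive median of 0.08 and a test direction downward), the receptor Ret (-1.08 ± 0.18).

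Some lists without a camera call still held single members past the threshold. Among p53 targets and apoptosis genes 3 of 23 rose and 1 fell (7, 5 higher and 2 lower, adjusted over the list alone; camera adjusted p = 0.209), with the kinase Plk2 at 0.94 ± 0.10. In enteroendocrine and tuft cells 1 of 12 rose and 2 fell (3, 1 higher and 2 lower, adjusted over the list alone; camera adjusted p = 0.261), with the tuft cell gene Avil at -0.62 ± 0.099. Epithelial-mesenchymal transition genes fell in 3 of 16 cases (3 adjusted over the list alone; camera adjusted p = 0.0916), and fatty acid and lipid genes in 2 of 20 (2 adjusted over the list alone; camera adjusted p = 0.863). Cytotoxic lymphocyte genes had 1 of 10 higher (0 adjusted over the list alone; camera adjusted p = 0.231), and adipocyte genes 1 of 7 (2 adjusted over the list alone; camera adjusted p = 0.193). B cell genes had 1 of 12 lower (0 adjusted over the list alone; median 1.03, camera adjusted p = 0.422), and smooth muscle genes 1 of 14 (1 adjusted over the list alone; camera adjusted p = 0.824). In Ilf3-KO replicate 4 alone, a single library and an alternative chosen after seeing the data, their medians were 2.18 and 0.82.

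The metallothionein gene Mt1, singled out after its values were seen, rose from 76.6 ± 4.49 to 285 ± 13.9 CPM (log2 fold change 1.90 ± 0.070, edgeR adjusted p = 1.67e-05, and 0.00996 with close pairs summed). Called genes made up 15.9% of those tested on chromosome 6 (156 of 984, adjusted p = 0.0298) and 9.05% on chromosome 13 (62 of 685, adjusted p = 0.0462) by Fisher's exact test of each chromosome against the rest. That test treats genes as independent, although neighbouring or co-regulated genes can move together, so its p-values may be too small.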
